A study of Homo sapiens with 6 samples.

How the data were processed

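RNA-seq libraries of Saos-2 cells, an established human osteosarcoma line, were compared after 24 h in 0.20 µM AIL or in the solvent DMSO. AIL is ailanthone, a quassinoid from the tree Ailanthus altissima, and the labels give this dose as its IC50. Each treatment had 3 replicates, and the titles of the samples gave the group and the replicate number. The labels call these biological replicates and do not say how the cultures were separated, so p-values here measure the spread between these 6 samples. Per the labels' protocols, cells were grown in 10% fetal bovine serum, and 1 µg of TRIzol RNA with a RIN above 8.0 entered an Illumina TruSeq RNA preparation. No batch or day was stated.

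The authors deposited a single table of TMM-normalized per-million read counts (CPM), per the file name, with values printed to 2 decimals. RSEM and edgeR 3.8.5 were used, per the submitters' processing notes, which give them no role. The aligner, genome build, annotation and use of strand are not given in the sources used here. Reads shared by near-identical, overlapping or antisense genes can therefore be counted for either gene. No gene coordinates are reported because the build was not stated. The table listed 13439 genes by symbol, and all per-sample columns in it were used. TMM scaling takes most genes as unaltered, so a shift of nearly all transcripts in 1 direction would not be seen in these values.

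Depth was read from the low values. They were whole multiples of a fixed step per library, equal to 1 read, and 99.95 to 99.98% of values up to 2000 reads lay within 0.2 reads of a whole number. The step was 0.0263 to 0.0307 CPM, which gives TMM-scaled library sizes of 32540000 to 38050000 reads. The condition for treating values as read counts was that 95% of them lie within 0.1 reads of a whole number. With rounding to 2 decimals this share was 52.4 to 65.1%, so the planned count test was left out and the analysis stayed on the log scale.

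Differences were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with empirical Bayes moderation and an intensity trend, two-sided and without covariates. The 11069 genes with a mean of at least 1 CPM over the 6 samples were tested. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. Log2 differences are AIL minus DMSO on the log2(CPM + 1) scale, which understates the change of low genes. Folds given as ratios are of mean CPM, but counts of genes by size of fold use the log2(CPM + 1) scale.

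Before the data were examined, 30 gene lists were fixed, and the 24 with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01, variance trend), with adjustment over these lists. The correlation estimated from the data was used as an alternative. Lists with fewer tested members were described by levels. The list of serine, glycine and folate metabolism follows the title of the study, which drew on these samples.

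Genes named in the text were taken by a rule fixed in advance. It took PHGDH, PSAT1, PSPH, SHMT1, SHMT2, MTHFD2 and PTGES3. It added the 12 highest and the 12 lowest log2 differences among calls with a mean of at least 5 CPM and no overlap between the groups, leaving out clone names. It also added up to 4 members of each fixed list with the smallest p. The rule drew on 5434 eligible genes and named 117, of which some are not reported here. Members of lists with fewer than 5 measured genes were described by levels, and any other gene is said to have been chosen after its values were seen.

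The test was tried on 1 simulated comparison of AIL against DMSO with 11058 tested genes. Genes were drawn independently from the DMSO means and the library sizes, with 1 dispersion taken from the DMSO replicates. At each of 4 sizes 50 genes were changed, and 1 further list was shifted by 0.25 on the log2 scale. The test recovered 18% of the genes changed by 0.2 on the log2 scale, 86% at 0.4, 98% at 0.8 and 100% at 1.2. Of its 179 calls, 15 (8.38%) were unchanged genes, and 0 of 24 random lists were called by camera. The real AIL replicates varied more than those of DMSO, and real lists hold correlated genes. These rates therefore do not carry over to the real calls of genes or lists.

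The replicate numbers were checked for pairing. Deviations from the group means correlated at 0.159, 0.133 and 0.129 between the DMSO and AIL samples of replicates 1, 2 and 3, above 0.1 in each pair. Samples of unlike number correlated at -0.179 to 0.0210. Deviations within a group cancel out, so the correlations are tied to each other, and the bound of 0.1 was not tested against chance. The pairing by number thus comes from the data alone and is uncertain. A fit with the replicate number as a block was made as an alternative. Pairs of replicates within a group differed by 1.76 to 5.52 times the variance of counting noise, so no pair looked like 1 library deposited a second time.

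The other alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 CPM, median-of-ratios scaling, quantile normalization, moderation without a trend, and leaving out each library. Sequence shared between genes was measured as the percent of 50-base words of a GENCODE release 29 transcript that also occur in transcripts of other genes. Length and GC content came from the same release for the 95.0% of tested genes matched by symbol. They were those of the longest transcript of each gene, protein-coding where the gene had one.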

Results

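The data were 6 RNA-seq libraries of Saos-2 osteosarcoma cells, 3 treated with DMSO and 3 with 0.20 µM ailanthone (AIL) for 24 h. The step of 1 read in each library gave TMM-scaled depths of 32540000 to 35830000 reads under DMSO and 35910000 to 38050000 reads under AIL. The listed genes summed to 84.4 to 85.0% of the scaled library in the DMSO libraries and to 85.7 to 87.2% in the AIL libraries. The first principal component held 72.4% of the variance and separated the treatments.

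The design asked which pathways AIL altered in these cells. Of the fixed lists, 27 of 30 genes of cholesterol and fatty acid synthesis, 21 of 28 of the endoplasmic reticulum unfolded protein response and 37 of 40 of mitosis fell. All 78 genes of cytosolic ribosomal proteins and 11 of 19 of the NRF2 antioxidant response rose (67 and 3 of the ribosomal genes were higher and lower with quantile normalization). These lists were called with the preset correlation of camera, and 0 of 24 lists with an estimated one. Of the mitochondrially encoded transcripts, held for RNA quality, 10 of 13 were lower in the same libraries. HMGCS1, which makes the HMG-CoA used for sterols, fell from 175.2 ± 3.16 to 83.5 ± 2.50 CPM (SD, n = 3). The autophagy receptor gene SQSTM1 rose from 291.7 ± 9.58 to 555.3 ± 27.9 CPM. Most changes were small. Of 11069 genes tested with limma, 3122 were higher and 2869 lower under AIL, 54.1% of those tested. Of these calls, 96.9% were under 1.5-fold on the log2(CPM + 1) scale, where 119 genes rose and 67 fell by at least 1.5-fold. The groups did not overlap for 60.1% of tested genes, against 10% by chance. On the log2(CPM + 1) scale, 10 genes were at least 2-fold higher and 4 at least 2-fold lower, and the groups did not overlap for 9 of the 10 and for all 4. These counts depended on the pseudocount, with 21 and 11 genes at a pseudocount of 0.1 and 4 and 2 at a pseudocount of 5. They also fell to 6 and 2 where a mean of 5 CPM was required.

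Serine is made from a glycolytic intermediate by PHGDH, PSAT1 and PSPH, and all 3 transcripts fell. PHGDH, the first enzyme of this pathway, fell by 35% from 37.7 ± 1.2 to 24.5 ± 2.21 CPM (SD, n = 3), a log2 difference of -0.60 with a standard error of 0.055 and a limma adjusted p of 7.96e-08. PSAT1 went from 106.2 ± 1.78 to 88.3 ± 2.46 CPM (log2 difference -0.26, SE 0.0306, limma adjusted p = 1.46e-06). PSPH went from 41.6 ± 0.398 to 34.1 ± 1.49 CPM (log2 difference -0.28, SE 0.0406, limma adjusted p = 1.75e-05). Of the enzymes that turn serine into glycine, cytosolic SHMT1 fell (log2 difference -0.20, limma adjusted p = 5.04e-04) and mitochondrial SHMT2 rose (0.15, limma adjusted p = 4.97e-04). The mitochondrial folate enzyme MTHFD2 fell from 214.7 ± 7.36 to 186.9 ± 6.40 CPM (limma adjusted p = 4.01e-05). Both GCSH and DLD of the glycine cleavage system fell by 0.42 and 0.30 on the log2 scale.

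Of the 17 tested members of the serine, glycine and folate list, 15 fell, SHMT2 rose and 1 did not pass. Adjusted over the list alone, 16 fell and 1 rose. The study chose this theme on these samples, so the counts are not independent evidence of its direction. The median log2 difference was -0.28 (camera adjusted p = 5.02e-06). With an estimated correlation the list was not called (adjusted p = 0.134). Mitochondrially encoded transcripts, a list held for RNA quality, were lower in the same libraries (median -0.20, 10 of 13 members lower).

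**Figure D1:**
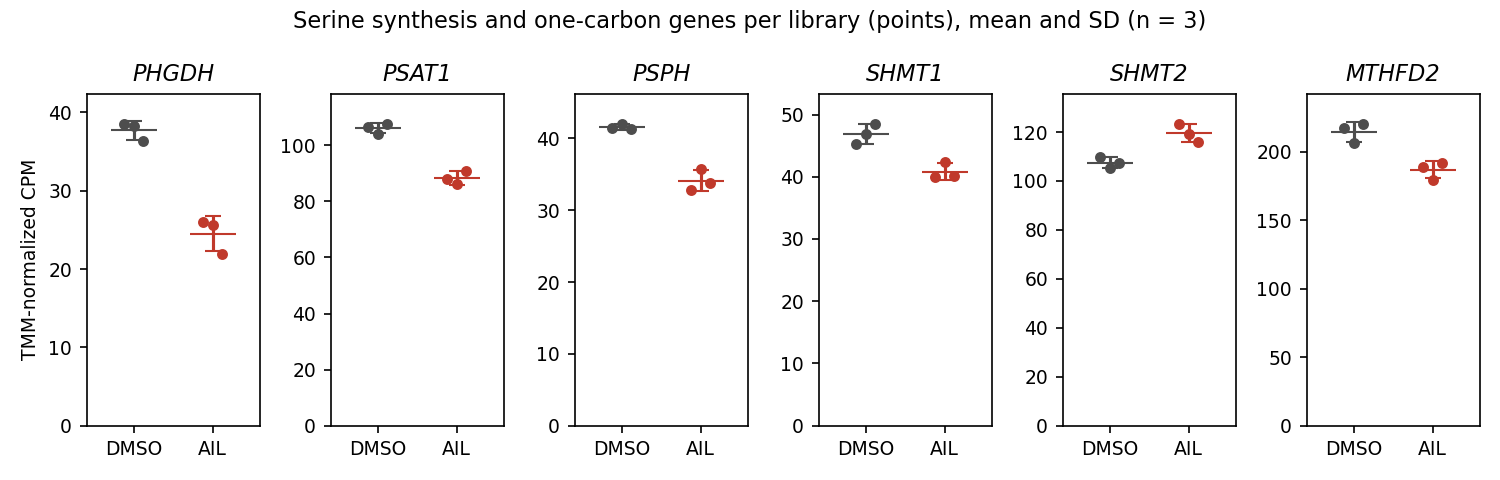
TMM-normalized CPM (y axis, from 0) of 6 genes of serine and folate metabolism in the 3 DMSO (grey) and 3 AIL (red) libraries, with points for libraries and bars for mean and SD. PHGDH fell from 37.7 to 24.5 CPM with no overlap, and of the 6 genes SHMT2 is the one that is higher under AIL.

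Genes of cholesterol and fatty acid synthesis had the lowest median among the lists tested, with 27 of 30 members lower and 0 higher. The median log2 difference was -0.52 (camera adjusted p = 6.52e-18, and adjusted p = 0.132 with an estimated correlation). Besides HMGCS1 (log2 difference -1.06, SE 0.0299, limma adjusted p = 1.21e-13), the fatty acid desaturase gene SCD fell from 566.6 ± 7.85 to 304.7 ± 5.83 CPM. SQLE, which oxidises squalene, fell from 259.2 ± 3.18 to 152.8 ± 1.35 CPM, and DHCR7, which acts at the end of sterol synthesis, from 138 ± 4.63 to 74.5 ± 4.93 CPM. CYP51A1 fell by 0.63 on the log2 scale, though 88.9% of its 50-base words also occur in another annotated gene, and the value is uncertain to that extent. MBTPS1, which encodes the site-1 protease that activates the SREBP regulators of these genes, fell by 47.1%, from 184.6 ± 2.89 to 97.7 ± 2.06 CPM (SD, n = 3; limma adjusted p = 2.04e-13). Mitochondrially encoded transcripts were lower in the same libraries, with a median of -0.20.

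Among genes of the endoplasmic reticulum unfolded protein response, 21 of 28 fell and 1 rose (median log2 difference -0.28, camera adjusted p = 1.04e-09). With an estimated correlation the adjusted p was 0.0702. The protein folding genes PDIA4, CALR, PDIA3 and HSP90B1 carried the smallest p-values. PDIA4 fell from 564.4 ± 5.93 to 305.6 ± 8.08 CPM (limma adjusted p = 1.32e-13), CALR from 928.3 ± 9.41 to 608.9 ± 5.65 CPM, PDIA3 from 524.3 ± 6.79 to 356.9 ± 3.46 CPM and HSP90B1 from 838.3 ± 11.97 to 571.8 ± 15.4 CPM (SD, n = 3). The mitochondrially encoded list stood at a median of -0.20 beside them.

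Cell cycle genes fell as well. In the G2/M and mitosis list, 37 of 40 members fell and 1 rose, with a median log2 difference of -0.31 (camera adjusted p = 6.52e-18, and adjusted p = 0.134 with an estimated correlation). The spindle gene ASPM fell from 424.3 ± 11.4 to 290.9 ± 6.003 CPM and the topoisomerase gene TOP2A from 727 ± 19.2 to 504.3 ± 12.7 CPM. TPX2 and PRC1, which organise spindle microtubules, each fell by 0.47 on the log2 scale, and 63.9% of the 50-base words of PRC1 occur in other genes. In the DNA replication and G1/S list, 26 of 41 fell and 2 rose (median -0.14, camera adjusted p = 5.93e-06, and adjusted p = 0.167 with an estimated correlation). RRM1, GINS1, PCNA and CLSPN fell by 0.36, 0.40, 0.35 and 0.29 on the log2 scale. The mitochondrially encoded list had its median of -0.20 in the same comparison. That list holds 13 tested transcripts, of which 10 fell and 0 rose (camera adjusted p = 5.10e-04, and adjusted p = 0.306 with an estimated correlation). MT-CO1 went from 1821 ± 42.4 to 1512 ± 40.3 CPM, MT-ND6 fell by 0.53 on the log2 scale, MT-CO2 by 0.23 and MT-CO3 by 0.19.

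In the list for epithelial-mesenchymal transition, migration and invasion, 15 of 24 members fell and 3 rose (median log2 difference -0.12, camera adjusted p = 9.22e-04). The adjusted p was 0.132 with an estimated correlation, and adjusted over the list alone 15 fell and 4 rose. FN1, which encodes the matrix protein fibronectin, fell from 2504 ± 68.1 to 1855 ± 26.6 CPM, and the integrin genes ITGB1 and ITGAV fell by 0.41 each on the log2 scale. MMP3, a matrix metalloproteinase gene, went the other way, from 17.7 ± 1.37 to 43.2 ± 2.28 CPM (SD, n = 3; log2 difference 1.24, SE 0.0545, limma adjusted p = 1.55e-11). Mitochondrially encoded transcripts again stood at a median of -0.20.

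All 78 genes of cytosolic ribosomal proteins rose, by 0.07 to 0.54 on the log2 scale with a median of 0.28 (camera adjusted p = 4.87e-28, and adjusted p = 0.141 with an estimated correlation). With quantile normalization, the median was 0.16, with 67 of the 78 higher and 3 lower, and after removal of a trend over transcript length, GC content and abundance it was 0.17. Mitochondrially encoded transcripts were lower in the same libraries, with a median of -0.20. RPL26 rose from 689.2 ± 13.9 to 1001 ± 16.5 CPM and RPL37 from 849.9 ± 5.88 to 1183 ± 19.6 CPM. RPS18 and RPL17 rose by 0.41 and 0.48 on the log2 scale. These genes have many processed copies, and 68.8, 39.2 and 28.6% of the 50-base words of RPL17, RPS18 and RPL26 occur in other genes. Of 35 ribosome biogenesis genes, 22 rose and 5 fell (median 0.11, camera adjusted p = 8.75e-04, and adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 22 rose and 6 fell. The nucleolar genes NOP56 and RRP9 rose by 0.32 and 0.44 on the log2 scale, RRN3, a factor of RNA polymerase I, by 0.29, and NPM1 by 0.33. For RRN3 and NPM1, 26.9 and 44.4% of the 50-base words occur in other genes.

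Of 19 genes of the NRF2 oxidative stress response, 11 rose and 2 fell (median log2 difference 0.19, camera adjusted p = 0.00145, and adjusted p = 0.167 with an estimated correlation). The ferritin light chain gene FTL rose from 444.1 ± 11.9 to 772.6 ± 32.0 CPM, and HMOX1, which degrades haem, from 441.2 ± 17.3 to 727.9 ± 31.5 CPM (SD, n = 3). NQO1 and TXNRD1, both reductases, rose by 0.53 and 0.42 on the log2 scale. OSGIN1 rose from 3.25 ± 0.182 to 8.58 ± 0.880 CPM (limma adjusted p = 3.53e-09). The mitochondrially encoded list, lower in the same libraries, had a median of -0.20.

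In the nuclear-encoded oxidative phosphorylation list, 15 of 34 members rose and 5 fell (median 0.06, camera adjusted p = 0.0474, and adjusted p = 0.626 with an estimated correlation). CYC1, SDHB, NDUFB5 and ATP5B rose by 0.27, 0.22, 0.29 and 0.17 on the log2 scale. The mitochondrially encoded transcripts of the same machinery went the other way (median -0.20, 10 of 13 lower). The oxidative phosphorylation call was close to the threshold. Its adjusted p was 0.0545 with a minimum mean of 5 CPM, 0.0609 with median-of-ratios scaling and 0.0882 without an intensity trend. Leaving out AIL replicate 1 gave 0.101, and leaving out DMSO replicates 1, 2 or 3 gave 0.0623, 0.0563 and 0.0551.

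**Figure D2:**
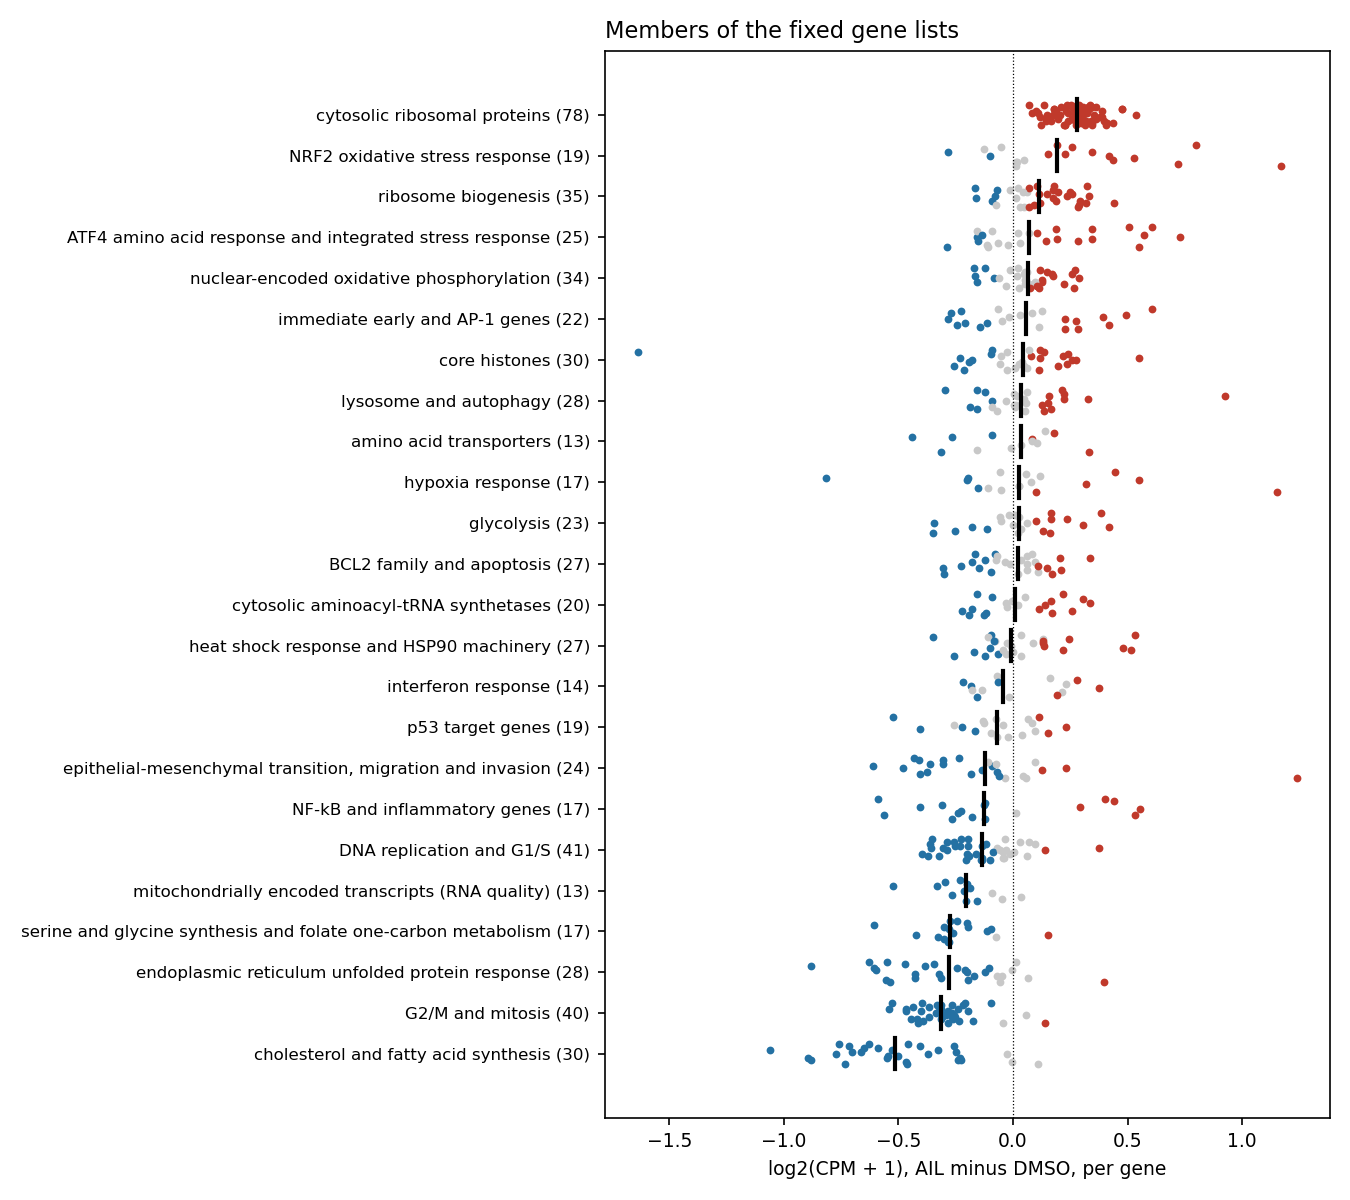
Log2 difference on the log2(CPM + 1) scale, AIL minus DMSO (x axis), of each tested member (point) of the 24 fixed lists with at least 5 tested members (number in brackets). Red and blue points passed the test as higher and lower, grey points did not, and black bars are list medians, from -0.52 for cholesterol and fatty acid synthesis to 0.28 for cytosolic ribosomal proteins.

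With the correlation estimated, 0 of the 24 lists were called at an adjusted p under 0.05, and 7 had an unadjusted p under 0.05. With the preset correlation, the real split of the 6 samples gave 11 called lists, and the other splits into 3 and 3 gave 5 to 10. Each other split mixes both treatments in unequal numbers and so keeps part of the AIL difference. These counts are therefore not a rate of list calls without a treatment effect. Counts adjusted over the list alone equalled those over all genes tested for the lists other than those where they are given.

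The remaining lists were not called. In the ATF4 and integrated stress response list, 12 of 25 genes rose and 4 fell (camera adjusted p = 0.133). ATF4 itself rose from 281.2 ± 4.74 to 399.8 ± 9.79 CPM, and STC2, ATF5 and PPP1R15A, which restores translation after stress, rose by 0.55, 0.57 and 0.73 on the log2 scale. For ATF4, 22.9% of the 50-base words occur in other genes. Among amino acid transporters, 3 of 13 rose and 4 fell (camera adjusted p = 0.981), and the median was above 0 while the mean and the test pointed below it. SLC7A5 and SLC3A2, which form a transporter of large neutral amino acids, rose by 0.33 and 0.18, and SLC7A6 and SLC1A4 fell by 0.44 and 0.26. Of 20 cytosolic aminoacyl-tRNA synthetases, 8 rose and 7 fell (camera adjusted p = 0.866), with KARS, FARSB and RARS higher by 0.30, 0.26 and 0.22 and TARS lower (-0.22).

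Of 27 heat shock and HSP90 genes, 8 rose and 8 fell (camera adjusted p = 0.869). Adjusted over the list alone, 8 rose and 9 fell, and the median was below 0 while the mean and the test pointed above it (the test turned below 0 with quantile normalization). PTGES3 encodes p23, an HSP90 co-chaperone reported to bind ailanthone, and rose from 410.6 ± 13.7 to 449 ± 13.4 CPM (log2 difference 0.13, limma adjusted p = 0.00119). HSPA1A and HSPA1B rose by 0.52 and 0.53, but share 72.6 and 73.5% of their 50-base words with other genes and cannot be separated. HSF1, the regulator of heat shock genes, rose by 0.48, and HSPA4L fell by 0.35.

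Among p53 target genes, 3 of 19 rose and 4 fell (camera adjusted p = 0.325). CCNG1 fell from 142.5 ± 2.01 to 98.7 ± 1.64 CPM, POLH and TNFRSF10B fell by 0.41 and 0.17 on the log2 scale, and ZMAT3 rose by 0.23. In the BCL2 family and apoptosis list, 6 of 27 rose and 9 fell (camera adjusted p = 0.710), with a median above 0 and a mean and test below it. MCL1 and BCL2L2, which oppose apoptosis, rose by 0.17 and 0.33, CYCS rose by 0.21, and APAF1, the apoptosome scaffold, fell by 0.30. In the lysosome and autophagy list, 10 of 28 rose and 6 fell (camera adjusted p = 0.387). SQSTM1 rose by 0.93 and ATG7 by 0.33 on the log2 scale, and LAMP2 fell by 0.16.

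For glycolysis, 9 of 23 genes rose and 5 fell (camera adjusted p = 0.605), and adjusted over the list alone 10 rose and 5 fell. GAPDH went from 3040 ± 43.1 to 3973 ± 119 CPM, ENO1 and ENO2 rose by 0.23 and 0.42, and the lactate transporter gene SLC16A1 fell by 0.34. For the hypoxia response, 5 of 17 rose and 4 fell (camera adjusted p = 0.680). ADM, which encodes adrenomedullin, rose by 1.15 and BNIP3 by 0.45, while ANGPTL4 fell by 0.82. Of 22 immediate early and AP-1 genes, 8 rose and 7 fell (camera adjusted p = 0.648), with DUSP1, DUSP5 and IER3 higher by 0.61, 0.42 and 0.49 and CYR61 lower (-0.21). In the NF-kB and inflammatory list, 11 of 17 fell and 5 rose (camera adjusted p = 0.125). ICAM1 and RELB fell by 0.56 and 0.59, and the cytokine genes IL6 and CXCL2 rose by 0.55 and 0.40. In the interferon list, 3 of 14 rose and 4 fell (camera adjusted p = 0.869), with a mean above 0 and a median and test below it. ISG15 and IRF9 rose by 0.38 and 0.28, although 100% of the 50-base words of IRF9 occur in another annotated gene, and OAS3 and IRF1 fell by 0.16 and 0.18. Of 30 histone genes, 12 rose and 8 fell (camera adjusted p = 0.593). Adjusted over the list alone, 12 rose and 9 fell, and the mean was below 0 while the median and the test pointed above it. HIST1H3A fell from 58.7 ± 3.198 to 18.2 ± 0.948 CPM, while HIST2H2AC, HIST1H1D and HIST1H3B rose by 0.55, 0.24 and 0.26. For HIST2H2AC, 30.5% of the 50-base words occur in other genes.

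Outside these lists, the genes that changed most among those with a mean of at least 5 CPM were of mixed kinds. The adhesion genes VCAM1 and ITGB8 fell from 7.68 ± 0.672 to 3.58 ± 0.2503 CPM and from 74.4 ± 1.72 to 39.8 ± 0.911 CPM (SD, n = 3). ADAM19, a membrane metalloprotease gene, fell by 48.9%, the spectrin gene SPTB fell by 50.6%, and NFE2L3, a transcription factor related to NRF2, went from 25.9 ± 0.860 to 14.3 ± 0.749 CPM. Higher under AIL were PSG4, a pregnancy-specific glycoprotein gene (6.85 ± 0.549 to 16.9 ± 0.643 CPM), the keratin-associated KRTAP2-3 (4.94 ± 0.191 to 12.9 ± 0.937 CPM) and NTN4, which encodes a netrin (16.0 ± 0.517 to 29.8 ± 1.23 CPM). Of the 50-base words of PSG4 and KRTAP2-3, 23.3 and 39.7% occur in other genes. The zinc finger genes ZNF329, ZBTB40 and ZSCAN12 rose by 0.94, 0.89 and 0.85 on the log2 scale, ID3, an inhibitor of DNA binding, by 0.84, and LRP11 by 0.83, with 80.8% of the 50-base words of LRP11 shared.

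**Figure D3:**
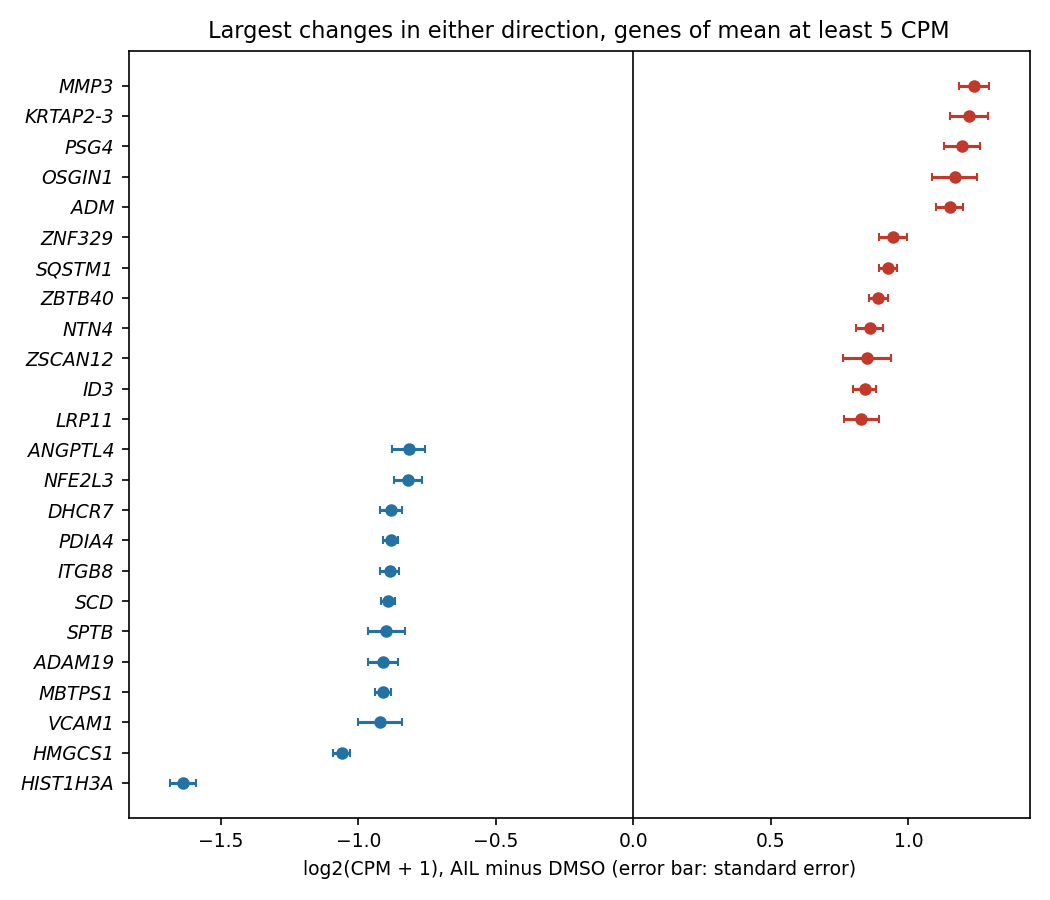
Log2 difference on the log2(CPM + 1) scale, AIL minus DMSO, with its standard error (x axis) for the 12 highest and 12 lowest calls among genes with a mean of at least 5 CPM and groups that do not overlap. The values run from -1.64 for HIST1H3A to 1.24 for MMP3.

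Some larger changes fell below the mean of 5 CPM and were chosen after their values were seen. DHRS2, a short-chain dehydrogenase gene, went from 0.747 ± 0.172 to 6.73 ± 0.295 CPM (SD, n = 3), a log2 difference of 2.15 with a standard error of 0.0943 and a limma adjusted p of 1.53e-11. LURAP1L rose from 2.75 ± 0.212 to 6.61 ± 0.723 CPM and UAP1L1 from 1.39 ± 0.164 to 3.88 ± 0.505 CPM. COL3A1, a collagen gene, fell from 7.09 ± 0.0361 to 2.86 ± 0.130 CPM, and the lipase gene LIPG from 2.75 ± 0.215 to 0.860 ± 0.140 CPM. Together with HIST1H3A and HMGCS1, these are the 4 genes at least 2-fold lower.

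Lists with fewer than 5 tested members are given as levels. Of the osteoblast genes, RUNX2 stood at 4.66 ± 0.295 and 4.72 ± 0.287 CPM under DMSO and AIL, and TNFRSF11B was lower (1.97 ± 0.332 and 1.36 ± 0.114 CPM, limma adjusted p = 0.0143, and 0.0616 and 0.0687 without DMSO replicates 1 and 2). Among metallothioneins, MT1E rose from 292.9 ± 2.06 to 386.1 ± 3.40 CPM, and MT2A stood at 678.9 ± 6.89 and 681.1 ± 31.9 CPM (lower with quantile normalization, limma adjusted p = 0.00169). MT1X stood at 9.23 ± 0.682 and 10.5 ± 0.339 CPM (limma adjusted p = 0.0372). Its adjusted p was 0.0658 without a filter and 0.108 with quantile normalization. It was 0.182 without DMSO replicate 3, and 0.0618, 0.0583 and 0.0881 without AIL replicates 1, 2 and 3. Of the blood and immune markers, CD68, a lysosomal protein gene of macrophages, was the 1 gene tested, and rose from 0.763 ± 0.0306 to 2.95 ± 0.412 CPM (limma adjusted p = 5.86e-08). Of the epithelial markers, the keratin genes KRT8 and KRT18 rose from 201.9 ± 3.76 to 230.7 ± 8.60 CPM and from 636.7 ± 9.41 to 724.9 ± 22.7 CPM, and KRT7 stood at 5.73 ± 0.662 and 5.40 ± 0.211 CPM. The endothelial markers ESAM and EGFL7 did not pass, at 12.7 ± 0.348 and 12.8 ± 0.826 CPM and at 1.11 ± 0.236 and 1.52 ± 0.257 CPM. EGFL7 had a limma adjusted p of 0.0682, and of 0.0492 without a filter, 0.0340 without DMSO replicate 2 and 0.0202 without AIL replicate 3. For the list of non-polyadenylated small RNA genes, 0 members were analysed here.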

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

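The alternatives were fixed before the data were examined. Genes named by the rule kept their direction and side of the threshold in 1637 of 1637 comparisons, and of 5991 calls the alternatives shared from 5215 (without DMSO replicate 2) to 5982 (replicate block). The serine genes PHGDH, PSAT1 and PSPH were lower in each. With the replicate block, 6468 genes were called, and the block changed no call of a gene named by the rule or of a list. It turned the direction of 1 uncalled list, amino acid transporters (adjusted p = 0.941). The share of calls that were higher was 52.1%, and 49.0 to 52.9% under the alternatives. The count test on whole reads was left out, since 52.4 to 65.1% of values lay within 0.1 reads of a whole number and 95% was required. Depth limits small changes in genes near 1 CPM, which is 33 to 38 reads.

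The counts of genes at least 2-fold higher and lower, 10 and 4, were 21 and 11 at a pseudocount of 0.1, 4 and 2 at a pseudocount of 5, and 6 and 2 with a minimum mean of 5 CPM. A higher pseudocount shrinks folds and a stricter filter tests fewer genes.

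With an estimated inter-gene correlation, 0 lists were higher and 0 lower, against 4 and 7, and 7 of 24 had an unadjusted p under 0.05. This test also takes the 4 residual degrees of freedom in place of those across genes. For the unfolded protein response and migration lists, the estimated correlation was 0.0087 and -0.018, below the preset 0.01. Their unadjusted camera p still rose, from 1.73e-10 to 0.0029 and from 3.46e-04 to 0.0166. The change in degrees of freedom, and not a higher correlation within these lists, raised it. For the other called lists, which part ended the calls was not tested. With the estimated correlation, adjusted p was 0.134 for serine, 0.0702 for the unfolded protein response, 0.141 for ribosomal proteins and 0.277 for ribosome biogenesis. It was 0.167 for DNA replication, 0.134 for G2/M, 0.132 for migration, 0.132 for cholesterol and 0.167 for NRF2. For oxidative phosphorylation it was 0.626, and for mitochondrial transcripts 0.306. Apart from oxidative phosphorylation, the highest adjusted p of these lists under the other alternatives was 0.00796 (NRF2). Oxidative phosphorylation ranged from 0.00729 to 0.626, with 0.0545 at a minimum mean of 5 CPM, 0.0609 with median-of-ratios scaling, 0.0882 without a trend, and 0.0184 to 0.101 on leaving out 1 library (DMSO replicate 1, 2 or 3 and AIL replicate 1 each ended the call, at 0.0623, 0.0563, 0.0551 and 0.101). The cause was not tested.

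Some uncalled lists turned direction: amino acid transporters without a filter (0.912), at a minimum mean of 5 CPM (0.770) and without DMSO replicates 1 or 3 or AIL replicates 1 or 3 (0.913 to 0.992), heat shock genes with quantile normalization (0.555), and interferon genes without DMSO replicate 2 (0.985, and 0.798 to 0.985 over the libraries left out). The cause was not tested.

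The 6 samples split into 3 and 3 in 10 ways, too few for a share under 0.05. As many limma calls came from 1 split, the real one (5991, highest other 0, with 6534 and at most 185 genes at an unadjusted p under 0.05). The same held for 2-fold changes (14, highest other 0; 1 split), serine genes (3, highest other 0; 1 split) and lists (11, highest other 10; 1 split). The other splits called 5 to 10 lists by camera with the preset correlation, and the 3 others that part the 3 pairs called 5 to 8. All of these splits mix both treatments within each group. That keeps part of the AIL difference between the groups and widens the spread within them. Neither the 0 gene calls nor the list calls of these splits therefore show what would be called without a treatment effect.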

Other observations

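The tests on site-1 protease, on near-identical copies and on zinc finger genes were chosen after the result was seen, as were the genes named in this part.

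Of the 8 listed pregnancy-specific glycoprotein genes, PSG4 included, 6 were higher under AIL in the limma fit without a filter on low values. PSG3 and PSG11 did not pass (limma adjusted p = 0.406 and 0.129). PSG1 stood at 0.260 ± 0.0721 CPM under DMSO and 1.52 ± 0.304 CPM under AIL (SD, n = 3), PSG9 at 0.703 ± 0.0651 and 2.26 ± 0.217 CPM, and PSG5 at 0.0667 ± 0.0115 and 1.11 ± 0.346 CPM. The family members are paralogs, and 23.3% of the 50-base words of PSG4 occur in other genes. Of 432 tested genes whose symbols begin with ZNF, ZSCAN or ZKSCAN, 191 were higher and 36 lower, with a median log2 difference of 0.12 (camera p = 1.18e-05, and p = 0.0334 with an estimated correlation). After a trend over length, GC content and abundance was removed, the median was 0.12. Mitochondrially encoded transcripts, a list held for RNA quality, were lower in the same libraries (median -0.20, 10 of 13 lower).

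Levels of some bone genes were low in both groups. SPP1 stood at 0.223 ± 0.0513 and 0.167 ± 0.0551 CPM, PHEX at 0.273 ± 0.107 and 0.200 ± 0.0557 CPM and MSX2 at 0.707 ± 0.182 and 0.770 ± 0.135 CPM under DMSO and AIL (SD, n = 3).

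Cholesterol and fatty acid synthesis genes fell under AIL, with a median log2 difference of -0.52. A trend over transcript length, GC content and abundance explained 4.19% of the variance in log2 difference over all genes. This trend, as measured, did not account for the fall, since the median was -0.53 after its removal. The 95% bootstrap interval was -0.63 to -0.37, with genes resampled as if independent. A candidate explanation is the lower MBTPS1, as the site-1 protease activates both SREBP and ATF6. The median of 12 ATF6 targets was -0.51 (11 lower and 0 higher) and that of 14 genes under XBP1 or PERK was -0.07 (5 lower and 2 higher), a difference of -0.44, but these groups were drawn up with the falls of PDIA4, CALR and HSP90B1 known, so it cannot support the explanation, which stays open. Protease protein and SREBP cleavage were not measured, MBTPS2 of the next cleavage step was higher (log2 difference 0.23, limma adjusted p = 0.00919, and 0.0600 without DMSO replicate 2), and a lower load on the endoplasmic reticulum or another regulator of these genes remains open.

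All 78 cytosolic ribosomal protein genes were higher (67 higher and 3 lower with quantile normalization), with a median log2 difference of 0.28. These transcripts are short and abundant, and removal of the length, GC and abundance trend lowered the median to 0.17 (95% bootstrap interval 0.15 to 0.22). Part of the rise may therefore follow that trend. How large a part was not settled, since the longest annotated transcript can exceed the usual one (7686 nt for RPL37). Scaling of the libraries alone did not account for all of the rise. The median was 0.16 with quantile-normalized values (0.15 to 0.23) and 0.27 with median-of-ratios scaling. The trend and the scaling were not removed together, so their joint share is not known. Both intervals resample genes as if independent, though the correlation within this list was estimated at 0.287. A biological effect of AIL on these transcripts is a hypothesis that stays open, and a shift in the RNA content per cell was not measured.

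HIST2H3A and DNAJC25-GNG10 differed widely between replicates of a group, from 1.27 to 132.7 CPM and from 2.09 to 19.3 CPM over the 6 libraries. The SD within groups was 59.0 CPM for HIST2H3A, 71.7 CPM for HIST2H3C and 33.3 CPM for their sum. It was 6.30 CPM for DNAJC25-GNG10, 3.18 CPM for DNAJC25 and GNG10 together and 3.24 CPM for all 3. Against partner values permuted within groups, the exact one-sided p of the SD of the sum was 0.0278 and 0.0833, and 0.0556 and 0.0833 after Holm adjustment for the 2 tests. The smallest p that the 36 arrangements can give is 0.0278. These tests replaced a ratio of SDs on the log2 scale, which the share of each copy in its sum could fix, and were run separately with both p-values known.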
